A study of mouse gut metagenome with 29 samples.

How the data were processed

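Stool of 15-month-old 5xFAD (AD) and wild-type (WT) mice with the diet labels CTRL, CELL and INULIN was profiled by 16S rRNA gene sequencing. DNA was extracted from fecal pellets with a fecal and soil microbe kit, target regions were amplified with barcoded primers, products were selected on 2% agarose, and 250 bp paired-end reads were made on an Illumina platform, per the labels' protocols. The values deposited by the authors were relative abundances, each the fraction of a sample's reads in 1 sequence variant with its taxonomy from kingdom to genus, per the file headers. The 1819 fractions of each sample summed to 1. The denoiser, the classifier, the reference database, the amplified region and the read depth are not given in the sources used here. With depth unknown, no counting error was computed, and a value of 0 means that a variant was listed at 0. Variants were 223 to 438 nt long (median 406 nt), and 1286 of 1819 (70.7%) were above 0 in 1 sample only.

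Groups followed the sample labels, which give genotype, diet and a number. The table also holds a mouse identifier that joins genotype and number and recurs across diets, but whether the same animal was sampled on each diet is not stated. All samples were therefore treated as separate, and the p-values measure spread between samples. The description of the series names a control, an inulin and a high fat diet, while the sample labels read CTRL, CELL and INULIN. Nothing in the sources ties CELL to the high fat diet, so the label is used as given. All 29 samples were kept.

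Fractions were turned into percent of reads and summed by genus, reads without a genus being pooled under their lowest named rank. Genera above 0 in at least 4 samples and with a mean of at least 0.01% were tested, 64 of 279 labels. Families and phyla were tested from a mean of 0.1%. Values were log2-transformed after adding 0.01, and 6 group means were fitted with limma 3.58.1 in R 4.3.3 with moderated variances. For each of 13 contrasts (9 comparisons of 2 groups, genotype averaged over diets and 3 interactions), p-values were adjusted by the Benjamini-Hochberg method over the taxa of 1 rank, and adjusted p under 0.05 counted as a difference. Genera are named by a rule fixed before the data were examined: the 8 highest and 8 lowest log2 changes among those passing, the 3 smallest p where under 3 passed, tested list members, phyla with a mean from 1% and families with a mean from 2%. Tests, alternatives and lists were fixed at the same time, apart from those named in the closing section.

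Community composition was compared by permutational analysis of variance on Bray-Curtis distances of variants, with 99999 permutations for the factors and exact enumeration for the 9 pairs of groups. Spread around group centres was tested with 9999 permutations. Shannon diversity was compared by two-sided exact permutation tests of the group means, and by permutation within strata for averages over diets or genotypes, adjusted over 9 and 4 comparisons. Distances, diversity and list tests used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures matplotlib 3.10.9. There were 12 lists of taxa: inulin responders, butyrate producers, mucus and mucin users, intestinal lactic acid bacteria, sulphate and sulphite reducers, Enterobacterales, Erysipelotrichaceae relatives, Bacteroidales polysaccharide users, immune-stimulating residents, diet-borne dairy bacteria, organelle and unplaced reads, and reagent contaminants. The summed percent of each list was compared by two-sided exact permutation tests on the log2 scale, adjusted over 108 tests, and list members were also adjusted over the list alone.

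The limma step was tested on simulated data for the genotype contrast on CTRL with 64 genera. Over 20 runs, it called 37.5% of genera changed by 1 on the log2 scale, 64.4% of those changed by 2, 100% of those changed by 4 and 1.25% of unchanged genera. For the permutation code, over 400 simulated comparisons of 5 against 5 samples, 5.5% of distance tests and 5.25% of mean tests passed without an effect, and 84% and 99.8% with one. That number of runs was raised from 40 after a first run. The effect added for the mean tests was larger than any Shannon difference reported below, so the 99.8% says nothing about smaller ones. Alternatives tried were added constants of 0.001 and 0.1, no filter, a mean of at least 0.1%, centring on the geometric mean of the genera, a fit of the compared groups alone, variance trend with robust moderation, the sample number as a block, an exact rank-sum test, other distances and diversity measures, and leaving out each sample in turn.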

Results

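The bacteria in stool of 15-month-old mice were profiled by sequencing the 16S rRNA gene. The mice were 5xFAD animals, labelled AD, or wild type (WT). Each sample carried 1 of 3 diet labels, CTRL, CELL or INULIN, and inulin is a fructan fibre that gut bacteria ferment. There were 29 samples, 15 AD and 14 WT, in 6 groups of 5 samples except WT CELL with 4. The deposited values were fractions of each sample's reads, and between 85 and 387 variants were above 0 per sample. Sequencing depth was unknown, so no counting error could be given and a value listed at 0 set no upper limit. A genus was assigned to 87.4% of reads on average (68.7% to 99.7% per sample), and 64 of 279 genus labels were abundant enough to test. The labels do not spell out what CELL stands for and name no cage, litter or sequencing batch. Differences between diet or genotype groups could therefore also come from housing or batch.

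Levels below are percent of reads, as mean ± SD over the samples of a group (n = 5, or n = 4 for WT CELL). Differences between groups are log2 differences of percent of reads plus 0.01 with their SE from limma, and each comparison covered 64 genera, 20 families and 5 phyla, corrected within the comparison and rank. The added 0.01 understates changes of genera near that level. One sample, WT INULIN replicate 1, had 90.8% of its reads in variants seen in no other sample (at most 0.262% elsewhere), so some WT INULIN levels are also given for the 4 remaining samples. Where only 1 level is given it includes replicate 1.

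Firmicutes, the phylum of most gut fermenters, and Bacteroidetes, which hold many polysaccharide users, made up most reads under the CTRL and CELL diets. On CTRL, Firmicutes stood at 65.9% ± 7.32 (SD, n = 5) in AD and 53.8% ± 11.4 (SD, n = 5) in WT mice. Under INULIN they were at 30.2% ± 5.24 in AD and 33.4% ± 4.33 in WT mice. Diet accounted for 52.3% of the variation in Bray-Curtis distances between samples, genotype for 11.3% and their interaction for 13.6% (permutation test, p = 1e-05 for each, the smallest that the permutations can give). In each of the 9 comparisons of 2 groups, the grouping explained between 37.8% (genotype in INULIN) and 84.1% (INULIN against CELL in AD) of the variation. Each exact permutation p was 0.00794, the smallest the design allows, and 0.00794 after correction over the 9 comparisons. The spread of samples around their group's centre differed between groups (F = 2.24, permutation p = 0.0267), with the widest in WT INULIN at 0.329 and the narrowest in AD INULIN at 0.120. Without WT INULIN replicate 1 the WT INULIN spread was 0.132 and the groups still differed (F = 5.44, permutation p = 0.002).

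**Figure D1:**
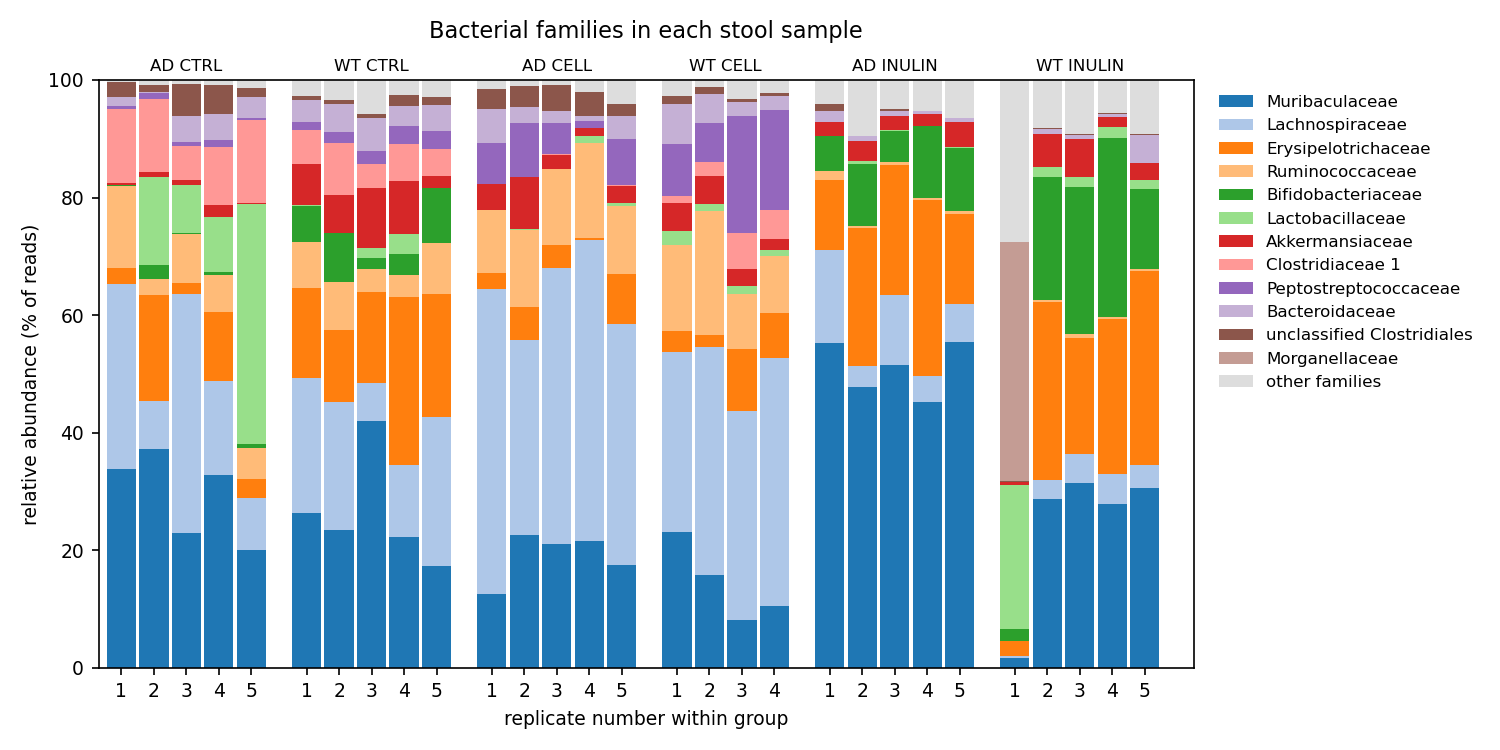
Share of reads (%) of 12 bacterial families and of all others in each of the 29 samples, stacked to 100% and grouped by diet and genotype. Under INULIN, the Lachnospiraceae held 8.38% (AD) and 3.55% (WT) on average, and WT INULIN replicate 1 differs from the other 4 samples of its group.

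**Figure D2:**
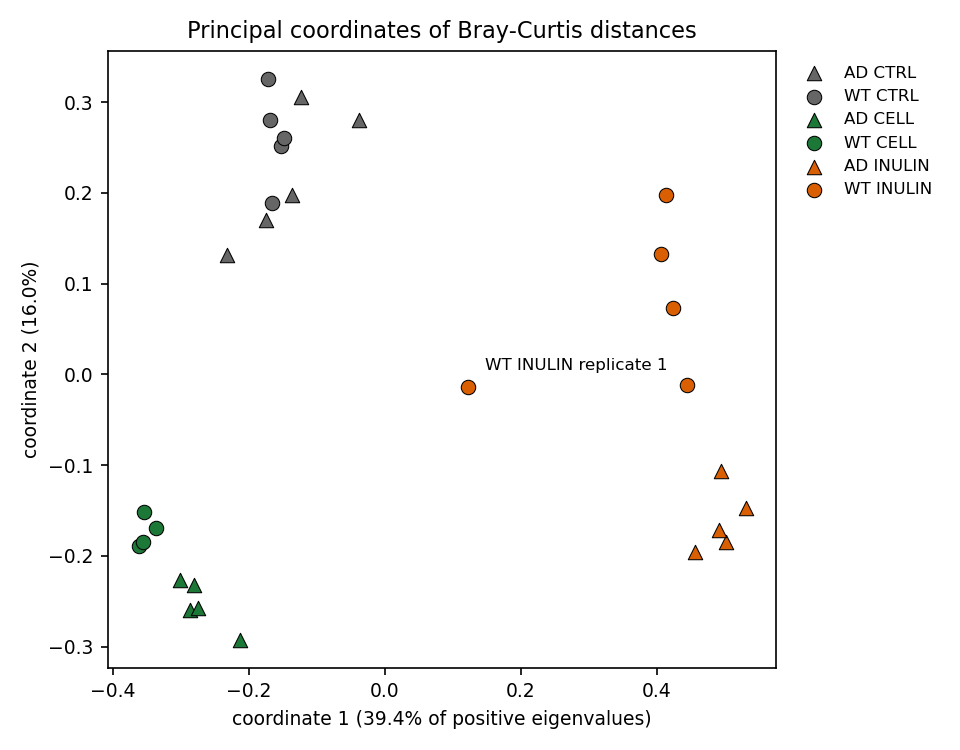
Principal coordinates of Bray-Curtis distances between samples, 1 point per sample (triangles AD, circles WT, grey CTRL, green CELL, orange INULIN). Coordinate 1 holds 39.4% and coordinate 2 holds 16.0% of the positive eigenvalues, and WT INULIN replicate 1 is labelled.

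On the CTRL diet, where the comparison asks which bacteria differ with genotype on the baseline diet, AD and WT mice differed in several genera of the Erysipelotrichaceae, a Firmicutes family common in laboratory mice. Faecalibaculum made up 13.7% ± 6.0 (SD, n = 5) of reads in WT mice and 0.00101% ± 0.00142 (SD, n = 5) in AD mice (adjusted p = 1.96e-24). Dubosiella and Ileibacterium held 3.19% ± 3.30 and 2.55% ± 2.86 in AD mice and were listed at 0 in all 5 WT samples (adjusted p = 2.16e-11 and adjusted p = 1.28e-12). The mucin degrader Akkermansia was lower in AD mice, at 0.801% ± 0.742 against 6.90% ± 3.11 (log2 difference -3.35 ± 0.64 (SE), adjusted p = 7.74e-05). So was Bifidobacterium, a fructan fermenter, at 0.817% ± 0.971 against 5.80% ± 3.09 (log2 difference -3.59 ± 0.73 (SE), adjusted p = 0.000134).

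In the Bacteroidales, unclassified Muribaculaceae (6.29% ± 1.66) and Alistipes (1.99% ± 1.15) were present in WT CTRL mice and listed at 0 in all 5 AD CTRL samples (adjusted p = 6.79e-20 and adjusted p = 7.03e-16). Among the Lachnospiraceae, the large family of spore-forming fermenters, Stomatobaculum reached 0.687% ± 0.304 in AD mice and was listed at 0 in WT mice (adjusted p = 1.26e-07). Acetatifactor was higher in AD mice (5.58% ± 3.25 against 0.985% ± 0.763; log2 difference 2.63 ± 0.52 (SE), adjusted p = 0.000112). Mediterraneibacter was lower (0.0166% ± 0.0172 against 0.507% ± 0.384; log2 difference -4.07 ± 0.63 (SE), adjusted p = 3.80e-06). Of the Ruminococcaceae, Neglecta was higher (1.06% ± 0.848 against 0.131% ± 0.0436), while Clostridium_IV (0.000529% ± 0.000753 against 0.154% ± 0.0907) and Ruthenibacterium (listed at 0 against 0.0819% ± 0.0591) were lower. Lawsonibacter and Sellimonas were higher in AD mice, by log2 differences of 3.58 ± 0.69 and 3.38 ± 0.77 (SE). Lactobacillus averaged 14.7% ± 15.5 in AD and 1.11% ± 1.47 in WT mice (log2 difference 3.65 ± 1.32 (SE), adjusted p = 0.0226), but 4 of 5 AD samples lay above all WT samples and the difference no longer passed when any of 6 samples was left out.

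In all, 29 of 64 genera differed by genotype on CTRL, 12 higher and 17 lower in AD mice. Measured relative to the geometric mean of all genera, 16 were higher and 14 lower. The groups did not overlap in 20 of all 64 genera, which chance gives in 0.794% of genera. The inulin responders, genera that rise under fructans in feeding studies, together held 4.48% ± 1.90 in AD and 30.8% ± 5.04 in WT mice (log2 difference -2.88, exact p = 0.00794, the smallest possible, adjusted p = 0.039 over 108 list tests). Of their 5 tested members, 3 were lower in AD mice, also when adjusted over the list alone. Mucus and mucin users were lower as well (3.65% ± 2.34 against 11.3% ± 3.28, log2 difference -1.90, adjusted p = 0.039), through 1 of 2 tested members, Akkermansia. Sulphate and sulphite reducers were scarce, at 0.000310% ± 0.000693 in AD and 0.0136% ± 0.00848 in WT mice (adjusted p = 0.039). Of 7 tested Erysipelotrichaceae relatives, 2 were higher and 4 lower in AD mice (3 and 4 when adjusted over the list alone). Of the 4, Amedibacillus and Turicibacter no longer passed relative to the geometric mean (-0.74 and -1.51, adjusted p = 0.133 and adjusted p = 0.0520), nor Amedibacillus with the sample number as a block (adjusted p = 0.0652). Turicibacter, Clostridium_XVIII and Amedibacillus were above 0 in all CTRL samples of both genotypes. Among families above 2%, Peptostreptococcaceae were lower in AD mice too (0.748% ± 0.330 against 2.32% ± 0.679; log2 difference -1.68 ± 0.46 (SE), adjusted p = 0.00538).

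On the CELL diet the genotypes were compared again, on a diet whose composition the labels do not give. Duncaniella, a polysaccharide-degrading genus of the Muribaculaceae, held 14.5% ± 3.10 (SD, n = 5) in AD mice and 2.42% ± 1.73 (SD, n = 4) in WT mice (log2 difference 2.93 ± 0.64 (SE), adjusted p = 0.000453). The unclassified Muribaculaceae went the other way, at 0.000456% ± 0.00102 in AD and 5.45% ± 4.01 in WT mice (adjusted p = 3.32e-18). Clostridium_sensu_stricto, the group of Clostridium proper, was lower in AD mice (0.103% ± 0.0615 against 3.66% ± 2.30; log2 difference -5.02 ± 0.47 (SE), adjusted p = 4.91e-10). Sellimonas made up 2.57% ± 1.07 in AD mice and was listed at 0 in all 4 WT samples (adjusted p = 3.16e-09).

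Kineothrix, a butyrate-forming member of the Lachnospiraceae, was also higher in AD mice on CELL (2.09% ± 1.45 against 0.155% ± 0.0814; log2 difference 3.56 ± 0.61 (SE), adjusted p = 2.37e-05). Blautia, an acetogenic genus, stood at 0.101% ± 0.0720 against 0.0125% ± 0.0114 (log2 difference 2.28 ± 0.47 (SE), adjusted p = 0.000280), and Clostridium_XVIII at 0.492% ± 0.425 against 0.0699% ± 0.0320 (log2 difference 2.37 ± 0.64 (SE), adjusted p = 0.00427). Neglecta was higher by 2.88 ± 0.46 (SE), and Harryflintia (0.0968% ± 0.0468) and Aminipila (0.0841% ± 0.0742) were listed at 0 in WT mice. Lower in AD mice were Acutalibacter (0.0351% ± 0.0258 against 0.805% ± 0.388), unclassified Ruminococcaceae (0.986% ± 0.214 against 4.08% ± 2.34), Clostridium_IV (0.0543% ± 0.106 against 0.176% ± 0.0390), Amedibacillus (0.0152% ± 0.0144 against 0.0572% ± 0.0262) and Eisenbergiella (0.0335% ± 0.0296 against 0.0898% ± 0.0373). Alistipes, at 0.397% ± 0.279 in WT mice, was listed at 0 in AD mice. The comparison passed for 20 of 64 genera (11 higher, 9 lower in AD). Of all 64 genera 18 were without overlap, which chance gives in 1.59% of genera. By the exact rank-sum test 22 genera had an unadjusted p under 0.05 and 0 passed after correction. Even genera without overlap had adjusted p = 0.0564 by that test. No list passed. Among butyrate producers 1 of 4 tested members, Flavonifractor, was higher in AD mice (0.398% ± 0.346 against 0.0610% ± 0.0127; log2 difference 2.05 ± 0.67 (SE), adjusted p = 0.0169), and among Erysipelotrichaceae relatives 2 of 7 were higher and 1 lower, the same when adjusted over the list alone.

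Under INULIN, where the question is whether the genotypes still differ on the fermentable fibre, Blautia stood out. It held 8.05% ± 5.23 (SD, n = 5) of reads in AD mice and was listed at 0 in all 5 WT samples (adjusted p = 9.11e-17). Duncaniella was also higher in AD mice, at 49.4% ± 4.98 against 18.7% ± 10.3, or 23.0% ± 3.71 (SD, n = 4) without WT replicate 1 (log2 difference 1.98 ± 0.60 (SE), adjusted p = 0.0153 over all samples). The facultative anaerobe Escherichia/Shigella was at 0.741% ± 0.349 in AD and 0.0291% ± 0.0281 in WT mice (log2 difference 4.49 ± 0.43 (SE), adjusted p = 1.81e-09). Clostridium_XlVa, a cluster of Lachnospiraceae, was lower in AD mice (0.0695% ± 0.0709 against 2.51% ± 1.37; log2 difference -4.87 ± 0.69 (SE), adjusted p = 1.41e-06). Mediterraneibacter, at 0.320% ± 0.293 in WT mice, was listed at 0 in AD mice.

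Clostridium_XVIII was higher in AD INULIN mice (0.615% ± 0.202 against 0.0941% ± 0.0941; log2 difference 3.02 ± 0.61 (SE), adjusted p = 0.000250). Longibaculum (0.0507% ± 0.0165) was listed at 0 in WT mice, and unclassified Clostridiales_Incertae_Sedis_XIII stood at 0.0870% ± 0.0786 against 0.000303% ± 0.000677. Unclassified Muribaculaceae (0.000532% ± 0.00119 against 0.0701% ± 0.0229), Adlercreutzia (0.0120% ± 0.00930 against 0.110% ± 0.114) and Anaerotruncus (0.000827% ± 0.000779 against 0.0447% ± 0.0458) were lower. These made 12 of 64 genera, 7 higher and 5 lower in AD mice, and 10 of all 64 were without overlap (0.794% by chance). By the exact rank-sum test, 16 had an unadjusted p under 0.05 and 0 passed after correction. Even genera without overlap had adjusted p = 0.0508 by that test. Without WT INULIN replicate 1, 19 genera differed, 8 higher and 11 lower, the same 12 among them. Butyrate producers, of which Oscillibacter (0.249% ± 0.165 against 0.0564% ± 0.0521) passed alone and 2 of 4 passed when adjusted over the list alone, held 0.371% ± 0.280 in AD and 0.0859% ± 0.0624 in WT mice (log2 difference 2.15, exact test, adjusted p = 0.039). Bacteroidales polysaccharide users were higher in AD mice (log2 difference 1.62, or 0.78 without WT replicate 1, exact test, adjusted p = 0.039 each), with 1 of 4 members higher and 1 lower. Intestinal lactic acid bacteria were lower (0.196% ± 0.200 against 1.99% ± 0.817, log2 difference -3.75, exact test, adjusted p = 0.039), as were sulphate and sulphite reducers (0.000213% ± 0.000476 against 0.0183% ± 0.0133, adjusted p = 0.039). Without replicate 1 the butyrate producers and lactic acid bacteria had log2 differences of 1.60 and -3.54 and adjusted p = 0.0659 each by the exact test. In both lists the genotypes still did not overlap.

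Averaged over the 3 diets, unclassified Muribaculaceae had the largest genotype difference, lower in AD mice on each diet (log2 difference -6.95 ± 0.20 SE, adjusted p = 2.13e-22). Alistipes (-4.13 ± 0.24) and Faecalibaculum (-3.39 ± 0.15) were lower in AD mice as well, although Faecalibaculum was near or at 0 in both genotypes outside CTRL. Alistipes was near 0 in both genotypes under INULIN (0.000396% in AD and 0.000202% in WT mice). Blautia (4.01 ± 0.26), Sellimonas (3.76 ± 0.45) and Clostridium_XVIII (2.22 ± 0.36) were higher in AD mice, although Sellimonas was listed at 0 in both genotypes under INULIN. In all, 35 of 64 genera differed on average, 17 higher and 18 lower in AD mice. Of the genotype differences of single diets, 14 genera passed in both CTRL and CELL (11 in the same direction), 3 in CTRL and INULIN (2 in the same direction) and 5 in CELL and INULIN (5), where independent calls would share 9.06, 5.44 and 3.75. Longibaculum passed in all 3 diets with different signs, at -1.58 in CTRL, 1.90 in CELL and 2.55 in INULIN.

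Inulin feeding was compared with CTRL within each genotype to ask which bacteria the fibre favours. In WT mice Dubosiella, listed at 0 on CTRL, reached 22.3% ± 12 (SD, n = 5), and 27.2% ± 5.66 (SD, n = 4) without replicate 1 (adjusted p = 2.73e-15). In AD mice it rose from 3.19% ± 3.30 to 19.9% ± 7.09 (log2 difference 3.37 ± 0.62 (SE), adjusted p = 2.13e-05). Olsenella, a lactic acid former of the Actinobacteria, was listed at 0 on CTRL and reached 4.54% ± 2.36 in WT (5.49% ± 1.19 without replicate 1) and 3.06% ± 1.14 in AD mice (adjusted p = 2.63e-17 and adjusted p = 7.30e-17). Bifidobacterium rose in AD mice from 0.817% ± 0.971 to 8.96% ± 3.13 (log2 difference 4.35 ± 0.73 (SE), adjusted p = 5.05e-06). In WT mice it went from 5.80% ± 3.09 to 18.4% ± 11 and did not pass with all samples (adjusted p = 0.0809), but at 22.5% ± 7.03 (SD, n = 4) without replicate 1 it did (adjusted p = 0.00706).

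Further rises under INULIN passed in AD mice. Blautia rose from 0.0132% ± 0.0128 to 8.05% ± 5.23 (log2 difference 8.36 ± 0.44 (SE), adjusted p = 6.34e-16). Akkermansia rose from 0.801% ± 0.742 to 2.89% ± 1.0 (log2 difference 2.21 ± 0.64 (SE), adjusted p = 0.00238), Parasutterella, an asaccharolytic proteobacterium, from 0.125% ± 0.103 to 2.06% ± 1.38 (log2 difference 3.81 ± 1.06 (SE), adjusted p = 0.00189), and Longibaculum from 0.00479% ± 0.00286 to 0.0507% ± 0.0165. In WT mice Parasutterella went from 0.451% ± 0.231 to 1.89% ± 1.22 and did not pass with all samples (adjusted p = 0.189), but at 2.35% ± 0.789 (SD, n = 4) without replicate 1 it did (log2 difference 2.44, adjusted p = 0.0391). Duncaniella rose from 16.4% ± 4.48 to 49.4% ± 4.98 (log2 difference 1.63 ± 0.60 (SE), adjusted p = 0.0159). Escherichia/Shigella was listed at 0 on CTRL in both genotypes. Under INULIN it stood at 0.741% ± 0.349 in AD and 0.0291% ± 0.0281 in WT mice (adjusted p = 5.24e-13 and adjusted p = 0.00222). It was above 0 in all 5 AD and in 4 of 5 WT INULIN samples, and the WT sample listed at 0 was replicate 1.

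Several Firmicutes of the CTRL community were lost from the table under INULIN. Turicibacter and Romboutsia, spore formers of the small intestine, held 4.60% ± 1.93 and 2.31% ± 0.678 in WT CTRL mice and 1.42% ± 0.988 and 0.748% ± 0.330 in AD CTRL mice. Both were listed at 0 in all 10 INULIN samples. Clostridium_sensu_stricto fell from 11% ± 3.22 to 0.000207% ± 0.000464 in AD mice and from 5.91% ± 1.88 to 0 in WT mice. Faecalibaculum, at 13.7% ± 6.0 in WT CTRL mice, was listed at 0 under INULIN, as were Ileibacterium, Stomatobaculum and Sellimonas of the AD CTRL mice. Acetatifactor fell in AD mice from 5.58% ± 3.25 to 0.000203% ± 0.000455 and Neglecta from 1.06% ± 0.848 to 0.00134% ± 0.00192. In WT mice unclassified Muribaculaceae fell from 6.29% ± 1.66 to 0.0701% ± 0.0229 (log2 difference -6.32 ± 0.34 (SE), adjusted p = 5.95e-16), Alistipes from 1.99% ± 1.15 to 0.000202% ± 0.000451, Kineothrix from 2.87% ± 2.87 to 0.00937% ± 0.0102 and Oscillibacter from 1.79% ± 0.803 to 0.0564% ± 0.0521 (log2 difference -5.17 ± 0.57 (SE), adjusted p = 3.72e-09).

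Counting all genera, 43 of 64 changed in WT mice (3 up, 40 down) and 51 in AD mice (11 up, 40 down), and of all 64 genera the groups did not overlap in 35 and 44 (0.794% by chance). The median log2 change of the 64 genera was -2.18 in WT and -2.43 in AD mice. Relative to the geometric mean of the tested genera, 21 came out higher and 24 lower in WT and likewise 21 and 24 in AD mice. The mean log2 change that this subtracts was -2.11 in WT and -1.81 in AD mice. A genus listed at 0 in both groups therefore comes out higher, as Ileibacterium does in WT and Ruthenibacterium in AD mice. Such genera can be among the 21. Without replicate 1, 44 genera changed in WT mice (5 up, 39 down), 41 of them shared with the full set. Butyrate producers fell from 3.13% ± 1.11 to 0.0859% ± 0.0624 in WT mice and from 2.17% ± 1.09 to 0.371% ± 0.280 in AD mice (log2 changes -5.35 and -2.59, exact test, adjusted p = 0.039 each). All 4 tested members fell in both genotypes, also when adjusted over the list alone, but relative to the geometric mean Butyricicoccus had a log2 change of 0.17 in WT mice and no member passed in AD mice. The inulin responders rose in AD mice (log2 change 2.32, exact test, adjusted p = 0.039), with 3 of 5 members up. In WT mice their share did not pass (30.8% ± 5.04 to 23.3% ± 12.5, or 28.5% ± 5.24 without replicate 1), and 2 of 5 members fell, of which Bacteroides no longer passed relative to the geometric mean (-0.57, adjusted p = 0.504). At phylum level Actinobacteria rose in WT mice from 6.16% ± 2.96 to 23.3% ± 12.3, or 28.1% ± 6.64 without replicate 1 (log2 difference 1.75 ± 0.68 (SE), adjusted p = 0.0282 over all samples) and in AD mice from 1.0% ± 1.08 to 12% ± 3.35 (log2 difference 4.34 ± 0.68 (SE), adjusted p = 3.30e-06).

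The other phyla and families moved as follows between CTRL and INULIN. Firmicutes fell in WT (log2 change -0.67 ± 0.16 SE, adjusted p = 0.00227) and AD mice (-1.14 ± 0.16, adjusted p = 1.74e-06). Proteobacteria rose in AD mice from 0.128% ± 0.104 to 2.84% ± 1.53 (log2 difference 4.47 ± 1.06 (SE), adjusted p = 0.000475). In WT mice they went from 0.486% ± 0.234 to 14.2% ± 26.4 (adjusted p = 0.0113), or 2.41% ± 0.773 (SD, n = 4) without replicate 1 (adjusted p = 0.0414). Ruminococcaceae, with many cellulose and starch users, fell from 6.49% ± 2.47 to 0.373% ± 0.241 in WT and from 7.30% ± 4.19 to 0.634% ± 0.457 in AD mice. Lachnospiraceae fell in WT mice from 17.8% ± 8.06 to 3.55% ± 1.94 (log2 difference -2.59 ± 0.60 (SE), adjusted p = 0.000513). In AD mice they went from 21.1% ± 14.5 to 8.38% ± 5.22 and did not pass (adjusted p = 0.0653). Most of that INULIN share was Blautia, a genus of this family, at 8.05% ± 5.23. Unclassified Lachnospiraceae went from 8.44% ± 6.60 to 0.219% ± 0.0728 in AD mice, so the family share does not mean that its other genera were kept. Bacteroidales polysaccharide users rose in AD mice (log2 change 0.83, exact test, adjusted p = 0.039). Enterobacterales passed in both genotypes (exact test, adjusted p = 0.039 each), from 0 to 8.83% ± 19.7 in WT mice, where replicate 1 held 44.0% and the other 4 samples 0.0364% ± 0.0265, and from 0.000219% ± 0.000491 to 0.775% ± 0.384 in AD mice. Diet-borne dairy bacteria, here Lactococcus, fell in AD mice from 0.0197% ± 0.0258 to 0.000297% ± 0.000665 (exact test, adjusted p = 0.039), although relative to the geometric mean Lactococcus changed by 0.59.

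**Figure D3:**
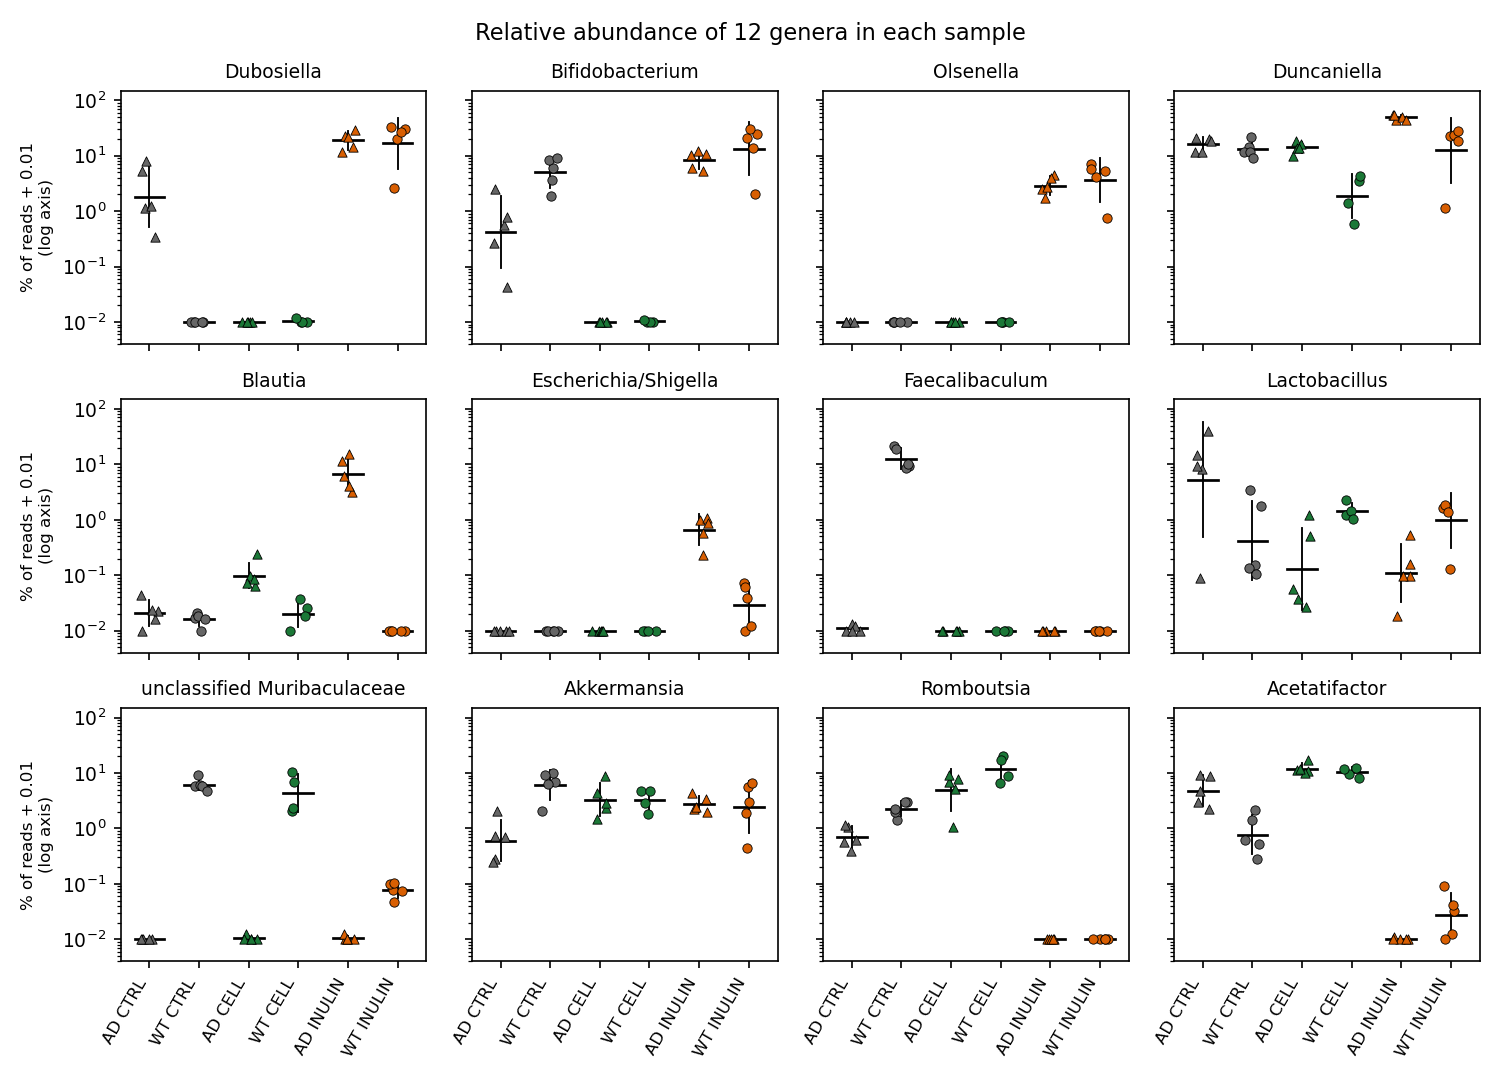
Relative abundance (% of reads + 0.01, log axis) of 12 genera in each sample by group, triangles AD and circles WT. Lines mark the mean and bars the SD on the log scale, and points at 0.01 are values listed at 0, as for Olsenella in all samples of the CTRL and CELL diets.

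CELL was compared with CTRL within each genotype to separate the effect of the third diet. In WT mice Stomatobaculum, listed at 0 on CTRL, reached 3.52% ± 1.68 (SD, n = 4), and Acetatifactor rose from 0.985% ± 0.763 (SD, n = 5) to 10.4% ± 2.04 (log2 difference 3.73 ± 0.55 (SE), adjusted p = 2.62e-06). Romboutsia rose from 2.31% ± 0.678 to 13.1% ± 6.35 in WT (log2 difference 2.41 ± 0.46 (SE), adjusted p = 9.69e-05) and from 0.748% ± 0.330 to 6.0% ± 3.10 in AD mice (log2 difference 2.80 ± 0.44 (SE), adjusted p = 8.38e-06). Bifidobacterium fell from 5.80% ± 3.09 to 0.000270% ± 0.000541 in WT mice and from 0.817% ± 0.971 to 0 in AD mice (adjusted p = 1.32e-10 and adjusted p = 7.97e-07). Faecalibaculum in WT mice and both Dubosiella and Ileibacterium in AD mice, the main Erysipelotrichaceae on CTRL, were listed at 0 on CELL.

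In WT mice Lawsonibacter rose from 0.0110% ± 0.0125 to 1.07% ± 1.03 (log2 difference 5.45 ± 0.73 (SE), adjusted p = 4.42e-07), unclassified Ruminococcaceae from 0.416% ± 0.0839 to 4.08% ± 2.34 (log2 difference 3.08 ± 0.50 (SE), adjusted p = 1.02e-05), Marvinbryantia from 0.0827% ± 0.0468 to 0.278% ± 0.0581, Pseudoflavonifractor from 0.145% ± 0.124 to 0.385% ± 0.146 and Eisenbergiella from 0.0341% ± 0.0231 to 0.0898% ± 0.0373. Duncaniella fell from 13.6% ± 4.70 to 2.42% ± 1.73 (log2 difference -2.81 ± 0.64 (SE), adjusted p = 0.000807), Kineothrix from 2.87% ± 2.87 to 0.155% ± 0.0814, Mediterraneibacter from 0.507% ± 0.384 to 0.000420% ± 0.000839 and Alistipes from 1.99% ± 1.15 to 0.397% ± 0.279. Ruthenibacterium (0.0819% ± 0.0591) and Sellimonas (0.207% ± 0.259) were listed at 0 on CELL. In AD mice Akkermansia rose from 0.801% ± 0.742 to 3.98% ± 2.93 (log2 difference 2.45 ± 0.64 (SE), adjusted p = 0.00271). Stomatobaculum rose from 0.687% ± 0.304 to 5.53% ± 3.51 (log2 difference 2.08 ± 0.76 (SE), adjusted p = 0.0310), a change that no longer passed relative to the geometric mean (1.85, adjusted p = 0.0531). Lawsonibacter, Marvinbryantia, Blautia, Anaerotruncus and Adlercreutzia rose by log2 changes of 2.71 ± 0.69, 2.25 ± 0.39, 2.25 ± 0.44, 2.21 ± 0.52 and 2.10 ± 0.61 (SE). Clostridium_sensu_stricto fell in AD mice from 11% ± 3.22 to 0.103% ± 0.0615 (log2 difference -6.81 ± 0.44 (SE), adjusted p = 2.64e-13), Lactobacillus from 14.7% ± 15.5 to 0.356% ± 0.511 (log2 difference -5.37 ± 1.32 (SE), adjusted p = 0.00173), Paramuribaculum from 12.9% ± 3.12 to 4.54% ± 1.78 and Acutalibacter from 0.107% ± 0.0591 to 0.0351% ± 0.0258. With the sample number as a block Paramuribaculum no longer passed in limma (adjusted p = 0.05885).

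Between CTRL and CELL, 17 of 64 genera changed in WT mice (8 up, 9 down; 13 up and 9 down relative to the geometric mean) and 27 in AD mice (20 up, 7 down; 14 up and 7 down relative to the geometric mean). The median log2 change was 0.03 in WT and 0.79 in AD mice. Of all 64 genera the groups did not overlap in 17 in WT (1.59% by chance) and 15 in AD mice (0.794% by chance). The exact rank-sum test gave an unadjusted p under 0.05 for 22 genera in each genotype, of which 0 passed after correction in WT and 15 in AD mice. In WT mice even genera without overlap had adjusted p = 0.0598 by that test. Inulin responders fell in WT mice from 30.8% ± 5.04 to 7.75% ± 3.59 (log2 change -2.10, exact test, adjusted p = 0.039), 2 of 5 members falling. Erysipelotrichaceae relatives fell in WT mice from 18.4% ± 6.44 to 5.95% ± 3.87 (log2 change -1.84, exact test, adjusted p = 0.039), 2 of 7 members falling, and in both lists the count was the same when adjusted over the list alone. No list passed in AD mice. Among phyla, Firmicutes rose in WT mice from 53.8% ± 11.4 to 76.1% ± 9.64 (log2 difference 0.52 ± 0.17 (SE), adjusted p = 0.0158) and Actinobacteria fell (-3.63 ± 0.73 SE, adjusted p = 0.000196), while Verrucomicrobia rose in AD mice with Akkermansia.

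The INULIN and CELL diets were also compared directly, a contrast that leaves CTRL out. Dubosiella, Bifidobacterium and Olsenella, all at or near 0 on CELL, made up 19.9% ± 7.09 (SD, n = 5), 8.96% ± 3.13 and 3.06% ± 1.14 under INULIN in AD mice. In WT mice they made up 22.3% ± 12 (SD, n = 5), 18.4% ± 11 and 4.54% ± 2.36. Duncaniella rose from 14.5% ± 3.10 to 49.4% ± 4.98 in AD (log2 difference 1.79 ± 0.60 (SE), adjusted p = 0.00970) and from 2.42% ± 1.73 to 18.7% ± 10.3 in WT mice (log2 difference 2.75 ± 0.64 (SE), adjusted p = 0.000336 over all samples). Without replicate 1 its WT INULIN level was 23.0% ± 3.71 (SD, n = 4). Romboutsia (13.1% ± 6.35 in WT and 6.0% ± 3.10 in AD mice on CELL), Turicibacter (5.80% ± 3.88 and 3.69% ± 2.60) and Stomatobaculum (3.52% ± 1.68 and 5.53% ± 3.51) were listed at 0 under INULIN. Acetatifactor fell from 10.4% ± 2.04 to 0.0278% ± 0.0332 in WT (log2 difference -8.55 ± 0.55 (SE), adjusted p = 5.00e-14) and from 12.2% ± 2.85 to 0.000203% ± 0.000455 in AD mice (log2 difference -10.20 ± 0.52 (SE), adjusted p = 2.57e-16).

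In AD mice Blautia rose from 0.101% ± 0.0720 on CELL to 8.05% ± 5.23 under INULIN (log2 difference 6.11 ± 0.44 (SE), adjusted p = 5.89e-13), Parasutterella from 0.706% ± 1.12 to 2.06% ± 1.38 (log2 difference 2.75 ± 1.06 (SE), adjusted p = 0.0231) and unclassified Clostridiales_Incertae_Sedis_XIII from 0.0252% ± 0.0138 to 0.0870% ± 0.0786. Escherichia/Shigella was listed at 0 on CELL in both genotypes. Kineothrix, Neglecta and Clostridium_XlVa fell in AD mice by log2 changes of -7.25 ± 0.58, -6.90 ± 0.43 and -6.13 ± 0.69 (SE), and Sellimonas was listed at 0 under INULIN. In WT mice Mediterraneibacter rose from 0.000420% ± 0.000839 to 0.320% ± 0.293 (log2 difference 4.40 ± 0.66 (SE), adjusted p = 9.07e-07). Unclassified Muribaculaceae fell from 5.45% ± 4.01 to 0.0701% ± 0.0229 (log2 difference -5.82 ± 0.36 (SE), adjusted p = 2.09e-14), unclassified Ruminococcaceae from 4.08% ± 2.34 to 0.0398% ± 0.0256, Intestinimonas, which forms butyrate, from 2.28% ± 0.443 to 0.0295% ± 0.0174 and Clostridium_sensu_stricto from 3.66% ± 2.30 to 0.

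This contrast passed for 45 of 64 genera in WT (6 up, 39 down) and 44 in AD mice (8 up, 36 down), and of all 64 genera 40 and 41 were without overlap (1.59% and 0.794% by chance). The median log2 change was -2.53 in WT and -2.17 in AD mice. Relative to the geometric mean, 24 came out higher and 26 lower in WT mice and 24 higher and 31 lower in AD mice. Paramuribaculum, lower in percent in AD mice, changed by 0.54. Here too the counts can hold genera listed at 0 in both groups, as Ileibacterium was in both genotypes. The same 45 genera passed in WT mice without replicate 1. Lachnospiraceae fell from 44.8% ± 7.84 to 8.38% ± 5.22 in AD (log2 difference -2.63 ± 0.60 (SE), adjusted p = 0.000344) and from 36.8% ± 4.92 to 3.55% ± 1.94 in WT mice (log2 difference -3.78 ± 0.64 (SE), adjusted p = 6.70e-06). All 4 tested butyrate producers fell in both genotypes, also when adjusted over the list alone, and their share fell from 4.36% ± 1.42 to 0.371% ± 0.280 in AD and from 3.97% ± 1.10 to 0.0859% ± 0.0624 in WT mice (log2 changes -3.69 and -5.73, exact test, adjusted p = 0.039 each). In WT mice without replicate 1 the change was -5.18, where 4 against 4 samples were too few for this test to pass. In AD mice inulin responders (log2 change 1.74), Erysipelotrichaceae relatives (2.70) and Bacteroidales polysaccharide users (1.45) rose and Enterobacterales went from 0 to 0.775% ± 0.384 (exact tests, adjusted p = 0.039 each). Relative to the geometric mean, Butyricicoccus did not pass in either genotype (-0.73 in WT and -0.27 in AD mice) and Flavonifractor did not in WT mice (-0.75).

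Whether the diet groups differed alike in both genotypes was tested by the interaction. The change from CTRL to INULIN differed for 29 of 64 genera, 16 with a higher change in AD mice, the change from CTRL to CELL for 24 (15 higher in AD) and that from CELL to INULIN for 20 (11 higher in AD). Blautia rose under INULIN in AD mice and was listed at 0 in WT mice, a difference against CTRL of 9.04 ± 0.63 (SE, adjusted p = 7.86e-13). Akkermansia rose in AD mice from 0.801% ± 0.742 under both other diets, while in WT mice it went from 6.90% ± 3.11 to 3.48% ± 2.54 under INULIN and 3.56% ± 1.49 on CELL (interactions 3.52 ± 0.90 and 3.34 ± 0.93 SE, adjusted p = 0.00198 and adjusted p = 0.00534). Lactobacillus fell in AD mice, from 14.7% ± 15.5 on CTRL to 0.169% ± 0.198 under INULIN, and stood at 1.11% ± 1.47 and 1.32% ± 0.691 in WT mice (interaction -6.83 ± 1.86 SE, adjusted p = 0.00337). Clostridium_sensu_stricto lost more of its share on CELL in AD than in WT mice (interaction -5.90 ± 0.64 SE, adjusted p = 1.45e-08). Across the 64 genera, the changes of the 2 genotypes correlated with Pearson's r = 0.556 and Spearman's rho = 0.512 for INULIN against CTRL, 0.255 and 0.249 for CELL against CTRL, and 0.803 and 0.690 for INULIN against CELL. These correlations are across genera, which are not independent replicates. Both genotypes passed for 35, 10 and 37 genera, in the same direction for 33, 8 and 36, where independent calls would share 34.3, 7.17 and 30.9.

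Diversity within samples followed diet. The Shannon index of variants was 3.59 ± 0.535 (SD, n = 5) in AD and 3.70 ± 0.295 in WT mice on CTRL, 4.34 ± 0.0691 and 4.16 ± 0.146 on CELL, and 2.59 ± 0.0829 and 2.67 ± 0.231 under INULIN. INULIN lowered it against CTRL by 1.03 in WT and 0.999 in AD mice (exact permutation tests, p = 0.00794, the smallest possible, adjusted p = 0.0143 over 9 comparisons). Against CELL the fall was 1.5 in WT and 1.75 in AD mice (exact test, adjusted p = 0.0143 each). On CELL it was higher than on CTRL by 0.466 in WT (exact test, adjusted p = 0.0357) and 0.748 in AD mice (exact test, adjusted p = 0.0143). The WT difference no longer passed when any 1 of the 4 WT CELL samples was left out. The genotypes did not differ detectably on CTRL (-0.105), CELL (0.177) or INULIN (-0.0748; exact tests, adjusted p = 0.746, 0.0816 and 0.652). Averaged over diets the genotype difference was -0.000933 (permutation test, adjusted p = 0.993 over 4 averaged comparisons), but with the Shannon index of genera it was -0.230 (permutation test, adjusted p = 0.00255), and under INULIN alone -0.418 (exact test, adjusted p = 0.0179). With the Shannon index of genera, the rise on CELL was not found in WT mice (-0.0248) or averaged over genotypes (0.130; permutation tests, adjusted p = 0.849 and 0.140). In AD mice that index was 2.59 ± 0.262 on CTRL and 2.87 ± 0.111 on CELL. Variants above 0 numbered 113 ± 6.76 in AD and 144 ± 50.6 in WT mice under INULIN, against 275 ± 24 and 317 ± 46.8 on CTRL.

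**Figure D4:**
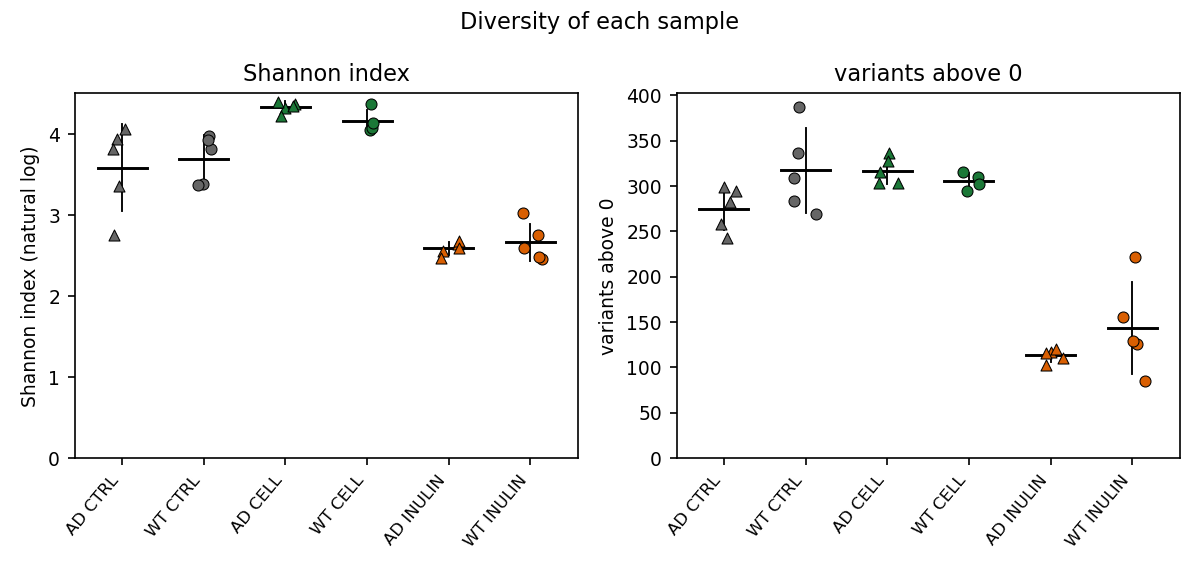
Shannon index of variants (natural log) and number of variants above 0 in each sample by group, with the mean as a line and the SD as bars. All INULIN samples of AD mice lie between 103 and 120 variants, below every sample of the CTRL and CELL diets (243 to 387).

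Of 12 lists of taxa fixed beforehand, 22 of 108 tests of their summed share passed. The immune-stimulating residents, in these data Akkermansia for the most part, passed in 0 of 9 comparisons by the exact test (smallest adjusted p = 0.0659), at 0.801% ± 0.743 in AD and 6.90% ± 3.11 in WT mice on CTRL, where Akkermansia alone passed in limma. Organelle and unplaced reads were at most 0.00646% ± 0.0139 in a group, in WT INULIN mice, and passed in 0 comparisons (smallest exact adjusted p = 0.696). Reagent contaminants, of which Delftia and Stenotrophomonas were tested, were at 11.1% in WT INULIN replicate 1, 0.00262% ± 0.00524 in the other 4 samples of that group and at most 0.00312% ± 0.00416 in the other groups, and passed in 0 comparisons (smallest exact adjusted p = 0.236). Intestinal lactic acid bacteria fell in AD mice by genus, with both tested members, Lactobacillus and Enterococcus, lower under INULIN than on CTRL (relative to the geometric mean Enterococcus no longer passed, at -1.09, adjusted p = 0.343), while their share went from 15.1% ± 15.9 to 0.196% ± 0.200 and did not pass the exact test.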

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

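The tests of explanations in this part were chosen after the results were seen, apart from the test for foreign bacteria in WT INULIN replicate 1, whose prediction was written after the sample was seen to lie apart and before that test was computed. Samples far from the others of their group were sought in 146 combinations of group and measure, limited after seeing the values to lists averaging at least 1% and groups reaching at least 0.1%. Of these, 18 held such a sample, where chance gives about 7.3 at 1 in 20, and 8 of the 18 were WT INULIN replicate 1.

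WT INULIN replicate 1 lay 0.728 from the centre of its group in Bray-Curtis distance. Proteobacteria made up 61.5% of its reads against 2.41% ± 0.773 (SD, n = 4) in the other samples of the group, Enterobacterales 44.0% and Lactobacillaceae 24.5%. Intestinal lactic acid bacteria stood at 3.43%. Bacteroidetes were down to 2.46% against 31.4% ± 3.11, Muribaculaceae to 1.62% against 29.6% ± 1.64 and the Bacteroidales polysaccharide users to 1.63%. Proteus (26.2%), Latilactobacillus (18.4%) and Acinetobacter (9.89%) were listed at 0 in all other samples, and Morganella (14.4%) was at most 0.00110% elsewhere.

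Among explanations for this sample, a mislabelled sample of another group is argued against, since over shared variants its mean distance to the nearest other group, AD INULIN, was 0.582 and to its own group 0.254. That test replaced a first version whose distances were all near their maximum. The listed reagent contaminants are argued against as the main source, as they held 11.6% of its reads from variants absent from the other 4 samples. Foreign bacteria added to an ordinary WT INULIN community are a candidate explanation: the 8.55% of reads in variants of the other 4 samples, rescaled, lay at a mean distance of 0.223 from them, within the range among those samples (0.138 to 0.323). Open are where and when these bacteria came in, including overgrowth in that animal, and no biological explanation was tested because the labels give none.

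Other samples stood apart in single measures. Bacteroidetes reached 51.6% in WT CTRL replicate 3, and Proteobacteria 2.70% in AD CELL replicate 5. In AD CTRL replicate 4, Verrucomicrobia and their family Akkermansiaceae were each at 2.06%, and the immune-stimulating residents, which hold the same genus, at 2.07%. AD INULIN replicate 1 had the highest Bacteroidaceae (1.87%), Ruminococcaceae (1.43%) and butyrate producers (0.864%) of its group. Bacteroidaceae stood at 4.78% in WT INULIN replicate 5 and Lactobacillaceae at 0.511% in AD INULIN replicate 2.

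The differences between diet groups were unlike in the 2 genotypes by the interaction test. Since cages are not given, diet and housing cannot be separated in these interactions. In Bray-Curtis distances the interaction held 13.6% of the variation, and 29 genera differed in their INULIN against CTRL change, 24 in CELL against CTRL and 20 in INULIN against CELL. A few genera passed in opposite directions in percent of reads. Longibaculum, scarce in all groups, rose in AD and fell in WT mice, with differences of log2 changes of 4.13 for INULIN and 3.48 for CELL against CTRL. Relative to the geometric mean its fall under INULIN in WT mice was not kept (-0.02, adjusted p = 0.965). Kineothrix rose on CELL in AD and fell in WT mice, with a difference of 5.44. For unclassified Clostridiales_Incertae_Sedis_XIII, which rose under INULIN in AD and fell in WT mice, the differences were 2.94 against CTRL and 3.61 against CELL. Its falls in WT mice were not kept relative to the geometric mean either (0.23 against CTRL and -0.33 against CELL, adjusted p = 0.673 and adjusted p = 0.544).

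As to whether the genotypes differed alike on each diet, the genotype changes across genera correlated with Pearson's r = 0.390 between CTRL and CELL (one-sided permutation p = 0.0698), 0.110 between CTRL and INULIN (p = 0.136, permutation) and 0.257 between CELL and INULIN (p = 0.0382, permutation). Only the last exceeded 95% of permuted values, so it stayed open whether the 64 genera as a set changed alike in CTRL and CELL and in CTRL and INULIN. Single genera did, as unclassified Muribaculaceae were lower in AD mice on each diet (-9.26 in CTRL, -8.71 in CELL and -2.88 in INULIN). A common difference was found for variants above 0 in at least 2/3 of the samples of 1 genotype and in none of the other. In both CTRL and CELL 51 were on the same side and 6 on opposite sides, in CTRL and INULIN 10 and 0, and in CELL and INULIN 8 and 0. Over all assignments of genotype in both diets the exact one-sided p was 3.15e-05 each, the smallest possible. These assignments were made separately in each diet, which takes samples of different diets as separate animals, and that is not known. With that of the second diet alone varied, the highest other numbers on the same side were 4, 3 and 1 (exact p = 0.00794, 0.00397 and 0.00397, the smallest possible). A first version drew random permutations. With the samples of all diets pooled, 31 variants were above 0 in most samples of 1 genotype and in none of the other. Of these, 25 were in AD and 6 in WT mice (one-sided permutation p = 0.0001, the smallest that the permutations can give). Most of the 25 were listed at 0 in all AD INULIN samples, as was 1 of Neglecta, and rest on CTRL and CELL alone. Separate resident variants in the 2 genotypes would give this pattern. These permutations too took samples of different diets as separate animals. Clostridium_XVIII had 1 variant in all 15 AD and no WT samples and another in all 14 WT and no AD samples. Since cages and litters are not given, genotype and housing cannot be separated, and either may give each genotype its own variants.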

How the results depend on the processing

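Chosen after the data were seen were the dispersion test without WT INULIN replicate 1 and the count of variants above 0.1%. The 12 tests of community composition kept their side of the threshold with square-root fractions, with presence alone, with distances of genera, with the block for the 3 factors and with each sample left out. Counts of genera, though not always the genera counted, stayed within 1.5 times the reported ones with no filter, a mean of at least 0.1%, an added constant of 0.1, centring, variance trend and a fit of the compared groups alone. The exact rank-sum test called 0 genera for genotype in CELL, for genotype in INULIN and for CELL against CTRL in WT mice, where 22, 16 and 22 genera had an unadjusted p under 0.05 and the smallest adjusted p were 0.0564, 0.0508 and 0.0598. Where it called 0, the groups did not overlap in 18, 10 and 17 of all 64 genera, the most extreme order this test can find. At these group sizes it called 24 for genotype in CTRL and 40 for INULIN against CELL in WT mice. Few samples alone do not give the 0. For CELL against CTRL in AD mice it called 15 genera in place of 27, and the added constant of 0.001 gave 15 as well. The cause of these lower counts in AD mice was not tested. Of the 396 genus calls in the 13 contrasts, 333 were also made after centring, 344 with no filter, 308 with a mean of at least 0.1%, 364 and 370 with added constants of 0.1 and 0.001, 358 with the compared groups alone, 384 with the block and 395 with variance trend. After centring the shared genera were 27 of 43 (WT) and 35 of 51 (AD) for INULIN against CTRL and 33 of 45 (WT) and 39 of 44 (AD) for INULIN against CELL. Genera called higher went from 3 to 21 and from 11 to 21 for INULIN against CTRL, and from 6 to 24 and from 8 to 24 for INULIN against CELL. The added ones can include genera listed at 0 in both groups, which centring alone moves up. Colidextribacter, named after its values were seen, passed in both directions for INULIN against CELL in WT mice, at -1.18 in percent and 0.88 after centring.

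Leaving out each sample in turn gave 25 to 32 genera for genotype in CTRL, 19 to 21 in CELL and 12 to 19 in INULIN, where the 19 came without WT INULIN replicate 1. For the diets it gave 42 to 46 (WT) and 48 to 50 (AD) for INULIN against CTRL, 15 to 22 (WT) and 18 to 30 (AD) for CELL against CTRL, and 44 to 45 (WT) and 42 to 44 (AD) for INULIN against CELL. Of 3414 values of named genera with a sample left out, 3276 kept their direction and side of the threshold and 138 no longer passed. Lactobacillus by genotype in CTRL ranged from 2.91 to 5.13. It no longer passed without AD CTRL replicates 2, 4 or 5 or WT CTRL replicates 1, 2 or 5, and neither with no filter nor with the compared groups alone. Over all alternatives its adjusted p ran from 0.000498 to 0.128. Of 1044 list values 946 stayed the same, and 25 of 108 list tests changed side at least once. In 324 of the 1044 the groups left, 4 against 4 or 5 against 3 samples, have a smallest exact p of 0.0286 or 0.0179, which cannot pass after correction. These say nothing about stability, and they hold all 27 changes of side of butyrate producers for INULIN against CELL in WT mice (-5.18 without WT INULIN replicate 1) and of inulin responders and Erysipelotrichaceae relatives for CELL against CTRL in WT mice. The other 71 changes fell on 22 tests that could pass. Among them, butyrate producers no longer passed for genotype in INULIN without WT INULIN replicate 1 (log2 difference 1.60, exact adjusted p = 0.0659) or without any 1 of the 5 AD INULIN samples, nor did lactic acid bacteria without any 1 of the 5 WT INULIN samples (-3.54 and exact adjusted p = 0.0659 without replicate 1). Enterobacterales passed for genotype in INULIN without WT INULIN replicate 1 (4.15, exact adjusted p = 0.0373). The cause of these was not tested.

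Centring on the geometric mean left 226 of the named values the same, 19 no longer passed and 4 changed sign. Amedibacillus and Butyricicoccus changed by 0.72 and 0.17 for INULIN against CTRL in WT mice, Lactococcus by 0.59 for INULIN against CTRL in AD mice and Paramuribaculum by 0.54 for INULIN against CELL in AD mice. None of the 4 passed. By construction, centring subtracts the mean log2 change of all tested genera, -2.11, -1.81 and -2.04 in these comparisons. With no filter 34 named values no longer passed, with the compared groups alone 25, with an added constant of 0.1 18 and with 0.001 11.

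Shannon diversity of genera in place of variants gave -0.0248 for CELL against CTRL in WT mice, 0.130 for that contrast averaged over genotypes and -0.230 for genotype averaged over diets (permutation test, adjusted p = 0.00255). Counting variants above 0, CELL differed from CTRL by -11.7 in WT mice and by 15.1 averaged over genotypes, and counting those above 0.01% by 20.4 averaged. The cause was not tested. The Shannon rise on CELL in WT mice ranged from 0.385 to 0.537 with a sample left out and no longer passed without any of the 4 WT CELL samples. Averaged over diets the Shannon difference between genotypes ranged from -0.0409 to 0.0682.

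Sample numbers recur across groups. Deviations from group means of same-numbered samples had a median correlation of 0.0189 between diets and -0.0931 between genotypes. Between diets they ranged from -0.321 to 0.337, and those of different-numbered samples from -0.524 to 0.399. Low correlations cannot show that the animals differed, so repeated sampling of the same animals stays possible. The main fit left the samples unpaired. With the number as a block, 22 genera in place of 27 passed for CELL against CTRL in AD mice and no count moved by more than 1.5 times. For the genotype contrasts that block was the number alone, which joins AD and WT samples. It cannot account for an animal sampled on several diets, so the genotype contrasts were not checked for this. Among named genera 241 values were the same and 8 no longer passed, with adjusted p from 0.0527 to 0.0679. These were Amedibacillus by genotype in CTRL and averaged over diets, Lactococcus averaged over diets and for INULIN against CTRL in AD mice, Paramuribaculum for CELL against CTRL in AD mice, Blautia and Lawsonibacter in the interaction for CELL against CTRL, and Adlercreutzia in that for INULIN against CELL. Pairwise community tests within numbers were not run, since their smallest exact p is 0.0625. Depth was unknown, so which scarce variants a sample missed cannot be told.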

Other observations

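All tests in this part were chosen after the results were seen, apart from the direction predicted for Bifidobacterium and Dubosiella. Under INULIN more genera fell than rose in all 4 comparisons. Shares sum to 100%, so genera that rise lower the share left for the others. That alone would scale all other genera alike, by the share left over. Against CTRL, 4 genera of at least 1% in WT mice without replicate 1 (Faecalibaculum, Clostridium_sensu_stricto, Turicibacter and Romboutsia) were listed at 0 in all INULIN samples, where the share left over gives 1.04% to 6.17%. In AD mice these were 3 (Ileibacterium, Turicibacter and Sellimonas), where it gives 0.0577% to 0.131%. From the lowest single AD CTRL samples it gives 0.0119%, 0.0314% and 0.0151% for them, close to the added 0.01. Against CELL they were 4 in WT mice without replicate 1 (Romboutsia, Turicibacter, Clostridium_sensu_stricto and Stomatobaculum; 0.769% to 2.86%) and 3 in AD mice (Romboutsia, Turicibacter and Sellimonas; 0.230% to 0.536%). In WT mice, where the share left over gives at least 0.769%, this argues against the loss of share as the whole cause for these genera. In AD mice less is expected and a 0 sets no upper limit. There it is weaker evidence in the comparison with CELL and decides nothing in that with CTRL.

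For the other genera not called higher, the median change lay -0.97 (against CTRL) and -0.61 (against CELL) from the share left over in WT mice without replicate 1, and 1.65 and 0.55 from it in AD mice. Of them 52.7%, 40.7%, 12% and 28.3% lay below it by more than 2 standard errors and 23.6%, 35.2%, 66% and 47.2% above it, in the same order. For these the loss of share and further falls cannot be told apart, because genera lay on both sides and the added 0.01 limits the falls of scarce ones. Earlier versions took only the genera called lower, whose choice favours large falls, all genera not called higher together, or all samples in WT mice, and were replaced after their values had been seen.

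Fewer variants under INULIN could also come from shallower sequencing, which would remove scarce variants first. Variants above 0.1% of reads, which shallow libraries see as well, were fewer by the same pattern. INULIN samples held 27 to 50 of them and the other samples 55 to 123, a difference against CTRL of -51.3 averaged over genotypes (permutation p = 4e-05). This argues against lower depth as the whole cause, and depth itself remains unknown.

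Each count of genera was compared with 100 splits of the same samples into groups of the same sizes, the real one included. For 11 of 13 contrasts 1 split, the real one, gave as many genera. The highest others were 18, 17 and 10 for genotype in CTRL (real 29), CELL (20) and INULIN (12), 40 and 39 for INULIN against CTRL in WT (43) and AD mice (51), 17 for CELL against CTRL in AD mice (27) and 39 for INULIN against CELL in AD mice (44). They were 17 for genotype averaged over diets (35), and 7, 17 and 17 for the interactions (29, 24 and 20). For CELL against CTRL and INULIN against CELL in WT mice 2 of 100 splits gave as many, the other being as high as the real one at 17 and 45, from splits with 8 of 9 samples on their own side. The highest others came from splits that left most samples on their own side in the comparisons of 2 groups, and the median of the others was 0, so chance assignment of samples is argued against for each count. Only 100 splits were drawn for each.

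Before it was computed, the correlation of Bifidobacterium with Dubosiella across the 10 INULIN samples was predicted to be negative. It came out positive, the test was then removed, and it was restored later with permutation within genotype. Over all orders within genotypes, Pearson's r was 0.552 (exact permutation p = 0.193) and Spearman's rho 0.600 (exact permutation p = 0.161). Without the 2 samples farthest from the median of Bifidobacterium, r was 0.793 and rho 0.857 (exact permutation p = 0.0972 and 0.0806). Without WT INULIN replicate 1, r was 0.373 and rho 0.450 (exact permutation p = 0.715 and 1). The prediction was not met, and no relation was detected. This was the only relation between 2 genera computed.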
